A study of Arabidopsis thaliana with 24 samples.

How the data were processed

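The series measures Arabidopsis thaliana transcripts on 24 one-colour arrays, 4 biologically independent replicates in each of 6 groups. The groups are enriched guard cells and whole leaves of the accession Col-0 collected in the light, enriched guard cells of gl1-1 plants sprayed with abscisic acid (ABA) or with a control solution, and enriched guard cells of Col-0 plants kept in dry or in humid air. Per the labels, plants grew in soil with 8 h light and 16 h dark at 22 and 16 °C under 100 µmol per square metre and second of white light. Guard cell and leaf samples of the first pair were taken after 5 h of light. The spray held 50 µM racemic ABA, of which 25 µM is the active form, with 0.01% Triton X-100, and tissue was taken after 4 h. Dry air was 20% relative humidity (tolerance 5%) for 4 h on plants of 6 to 7 weeks, and humid air was above 85% by the sample labels and above 80% by the treatment protocol. Total RNA was purified on columns and labelled with Cy3 together with spike-in RNA.

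Each array was scanned and read with Agilent Feature Extraction, per the file headers. The processed signal in the deposited scanner files is an intensity that the authors' software had background-subtracted and corrected for trends across the array, without scaling between arrays. The same deposited files give the mean signal and the local background of each spot as intensity, and flags of 0 or 1, among them whether a spot is well above background. The deposited value table holds log2 values; all its columns have the same quantiles, with column medians between 8.276 and 8.282, so they were read as quantile normalized, and they were not background-subtracted. In 18 of its columns the order of the spots is that of the mean signal in the scanner file of the same sample, and in 6 it differs slightly (lowest rank correlation 0.992). The software used for that scaling is not given in the sources used here. Results come from the scanner files, with the value table as an alternative. The array read with another version of the reading protocol, ABA replicate 4, held processed values at or below 0; 205 of its probes were set to a floor of 0.0014 times the array's 75th percentile.

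The processed signal was taken as log2 minus the log2 of the array's 75th percentile. Of 45220 spots, 1417 are controls; 43603 distinct plant probes remain, 38413 of them with a locus in the annotation on the array, for 29030 loci. A gene was represented by its probe with the highest mean over the 24 arrays (7320 loci had more than 1 probe); 668 genes rest on a probe that lists more than 1 locus. Probes without a locus were kept out of the gene comparisons. Loci and symbols were checked against the reference gene table, and coordinates were not used. One linear model with the 6 groups was fitted to all arrays with limma 3.58.1 (lmFit and eBayes, 18 residual degrees of freedom) in R 4.3.3, with the data.table package (version 1.17.8) to read the files and matplotlib (version 3.10.9) for the plots. A gene was tested where its probe was well above background on at least 3 of the 4 arrays of a compared group. P-values were adjusted with the Benjamini-Hochberg method per comparison, with a threshold of 0.05. Log2 values and errors quoted are the limma coefficient and its standard error, with n = 4 arrays per group unless another n is given.

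The comparisons were guard cells over leaf, ABA spray over control spray, low over high humidity, and the ABA effect minus the humidity effect. They, the tests, 22 gene lists and the rule for naming genes were fixed before the data were examined. The text names, per comparison, the 6 genes with a symbol that rose most and the 6 that fell most among those well above background on at least 3 arrays of both groups and with no overlap between the groups; the 3 called genes per direction with the largest change that were not well above background on any array of the lower group, given as bounds; the 3 called members with the largest change in each list past its test; and a fixed set of guard cell, photosynthesis and ABA genes. For the difference it names 5 genes per direction. A bound is the fold between the mean log2 values of the groups. Before that, values of the dimmer group below the lowest well-above-background signal of their array were raised to it. A bound carries no error and depends on the background setting, so "at least" is not a confidence limit. Other list members quoted were chosen after their values were seen. Of 330 list entries, 327 were matched to a locus on the array; a member whose symbol belongs to another locus was left out. Lists were tested with camera of limma with a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison; an estimated correlation and fry were run beside it. Per-array list means were compared with an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286.

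Simulated data took the mean and residual SD of each gene from these arrays, with independent normal noise and the same numbers of arrays. On them the pipeline recovered 70.1%, 68.7% and 70.1% of genes changed by 1 log2 unit in the 3 treatment or tissue comparisons. Of those changed by 0.5 it recovered 29.9%, 23.9% and 43.3%. False calls made up 6.77%, 4.88% and 4.26% of the calls. The list that had been shifted was called, and 0 of 20 lists left alone were. Genes varied independently there, whereas members of the real lists correlate. In guard cells over leaf the estimated correlation was 0.234 for guard cell genes and 0.658 for mesophyll genes. The simulation therefore cannot tell how often camera with its preset correlation calls a real list falsely. Per comparison only 67 genes were changed by 0.5, 67 by 1 and 66 by 2 log2 units, far fewer than the real comparisons called. The adjusted threshold depends on that share, so these recovery rates need not hold for the real data. Changes were added to scaled values, so the scaling was not tested.

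Replicate numbers were checked as a possible pairing. After the group means were taken out, ABA and control arrays with the same number correlated at 0.251, 0.17, 0.467 and 0.481. Each was above every other number (highest others -0.066, 0.052, 0.012 and 0.095), so the numbers may pair these samples. The labels state no pairing and the model without it was kept; with replicate as a block the counts were 3279 higher and 3737 lower, and blocked values are given where a call changes. Guard cells and leaf were each on a slide of their own and scanned on days of their own, and low and high humidity on a slide each on a shared day, so slide cannot be told apart from group there. ABA replicates 2 and 4 were scanned on the day of the controls and replicates 1 and 3 on another. With scan date as a block the ABA effect thus rests on ABA replicates 2 and 4, as it does with arrays of that day only. The ABA arrays were on 2 slides, 1 for each of these scan days, and the controls on another. No slide held both, so slide cannot be told apart from spray either.

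Alternatives tried were quantile normalization, a median shift, normexp background with an offset of 50, no filter on dim probes, a stricter one, the mean of a gene's probes, the value table, only the arrays compared, array weights, blocks for replicate, scan date and slide, a threshold of 0.01, a 2-fold minimum, and leaving out each array. Added after seeing the data were normexp with local backgrounds above 2 times the array's median set to it (capped), arrays of 1 scan day only, 1 background rule for all arrays, and leaving out guard cells replicate 4 and ABA replicate 4. A few spots with very high local backgrounds stretched the planned normexp fit. Values given with normexp are from that planned setting unless capped is said. Under it 39 values of named genes lost their call and 6 turned. With capped backgrounds 11 lost their call and none turned.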

Results

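Transcripts were compared between enriched guard cells and whole leaves, between guard cells sprayed with the drought hormone abscisic acid (ABA) and with a control solution, and between guard cells from dry and humid air. Each of the 6 groups has 4 arrays, 24 in all. Their number limits the precision, and the median standard error of a log2 fold change was 0.158, 0.172 and 0.154 in the 3 comparisons.

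Replicates correlated at 0.974 to 0.994 across genes. The share of probes well above background was 77.41 to 91.54% in guard cells, 71.13 to 75.94% in leaf, 85.29 to 92.1% with ABA spray, 78.88 to 87.39% with control spray, 73.15 to 78.7% at low and 71.55 to 78.57% at high humidity. Guard cells replicate 4 (91.54%) and ABA replicate 4 (92.1%) stood above the other arrays of their groups. GL1, the trichome regulator mutated in the sprayed gl1-1 plants, was well above background on 1 guard cell and 1 high humidity array and on 0 arrays of the other groups, so the genotype was not checked from its transcript. Other transcripts do part the gl1-1 from the Col-0 arrays, and they put low humidity replicate 1 between them. On that array 74 genes, chosen without it as over 4-fold higher on every gl1-1 array than on any other Col-0 array, had a median of 0.454 of the gl1-1 signal (quartiles 0.302 and 0.576). With genes chosen without both that array and the array looked at, this share was -0.005 to 0.018 on the other Col-0 arrays and 0.884 to 1.066 on the gl1-1 arrays. With low humidity replicate 1 kept among the Col-0 arrays only 9 to 17 genes remained, and the share was -0.013 to 0.069 and 0.529 to 1.317. These genes were looked at only after the other results were seen. All gl1-1 arrays were sprayed and no Col-0 array was, so the genes part spray as well as line. Low humidity replicate 1 stayed in the fit, as fixed beforehand, and the values in dry air without it are given with that comparison.

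Which transcripts set guard cells apart from the leaf as a whole was the question of the first comparison. Transcripts of the ion transport that drives stomatal movement were several-fold higher in guard cells: GORK (AT5G37500), the potassium channel through which guard cells lose potassium on closing, was 10.8-fold higher (log2 3.43, SE 0.155, n = 4 per group, adjusted p = 4.48e-12), and the anion channels ALMT12 (AT4G17970) and SLAC1 (AT1G12480) were higher by log2 3.20 (SE 0.188) and 3.04 (SE 0.189). The guard cell transcription factors FAMA (AT3G24140) and MYB60 (AT1G08810) were higher by 2.77 (SE 0.164) and 2.73 (SE 0.172). PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, was lower (log2 -2.29, SE 0.198), and so was CA1 (AT3G01500), a carbonic anhydrase (-1.95, SE 0.207).

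Of the 20 guard cell genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median log2 fold change of 2.62 (camera adjusted p = 6.91e-09). The list had adjusted p = 0.0984 with an estimated correlation, and the exact permutation p of its array means was 0.0286, the smallest that 4 against 4 arrays can give. After GORK came BLUS1 (AT4G14480), a kinase of blue-light stomatal opening, at 3.24 (SE 0.15), and KAT1 (AT5G46240), a channel for potassium uptake, was at 2.07 (SE 0.239). OST1 (AT4G33950), a kinase of ABA signalling, was 4.27-fold higher (SE of the log2 value 0.136). The members not called were PHOT1 (-0.03), SLAH3 and TGG2 (-1.52, adjusted p = 0.0969). The ion transport list, which shares 8 genes with that list, held 17 higher and 1 lower of 27 (median 1.29, adjusted p = 3.55e-05, and 0.0319 with an estimated correlation). The lower one was the aquaporin PIP2;1 (-1.56). Of the stomatal lineage list, genes of the asymmetric divisions that precede guard cells, 9 of 12 were higher and 0 lower, also adjusted over the list alone (median 2.22, adjusted p = 0.00764). It had adjusted p = 0.695 with an estimated correlation and 0.0807 with normexp background. The peptide EPF2 (AT1G34245, 3.04, SE 0.625), POLAR (AT4G31805, 2.99, SE 0.534) and the transcription factor SPCH (AT5G53210, 2.81, SE 0.44) were dim in leaf, well above background on 2, 1 and 2 of its arrays. Single leaf arrays moved them: EPF2 was at 3.69 without leaf replicate 1 and 2.32 without leaf replicate 3, and POLAR at 3.68 without leaf replicate 4. Normexp background ended these 3 calls (adjusted p = 0.82 for EPF2 and 0.919 for SPCH) and turned POLAR to -0.02.

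All 18 mesophyll and photosynthesis genes were lower, also adjusted over the list alone (median -1.25, adjusted p = 6.91e-09). That list had adjusted p = 0.521 with an estimated correlation. GLDP1 (AT4G33010), a glycine decarboxylase subunit of photorespiration, fell by log2 2.12 (-2.12, SE 0.149), and LHCB3 (AT5G54270), a light-harvesting protein, was at -1.38 (SE 0.204). RBCS1A (AT1G67090), a Rubisco small subunit, was at -0.65 (SE 0.173, adjusted p = 0.00313), and turned to 0.08 with quantile normalization and 0.13 in the value table of the series. All 18 were well above background in guard cell samples too, as were all 20 guard cell genes in leaf. Markers of other epidermal cells were mixed. Of the epidermis and cuticle list 11 genes were higher and 2 lower of 20 (median 0.53, adjusted p = 0.189), and of the trichome list 8 and 4 of 12 (median 1.25, adjusted p = 0.271), with TTG2 at 3.13 (0.38, adjusted p = 0.804, with normexp). Of 14 vasculature genes 6 were higher, among them the phloem sucrose carrier SUC2 (1.78), and the list did not pass (median 0.30, adjusted p = 0.113), except without guard cells replicate 4 (adjusted p = 0.0412).

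ABA genes differed one by one. ABA1 (AT5G67030), zeaxanthin epoxidase, was lower (-1.34, SE 0.101), while NCED5 (AT1G30100), a dioxygenase of ABA synthesis, was higher (1.43, SE 0.353, but -0.01 with normexp), as were ABA3 (0.69) and ABA2 (0.52), whose calls were lost with the median shift (adjusted p = 0.0998 and 0.124). CYP707A1 (AT4G19230), an ABA hydroxylase, was higher (2.67, SE 0.442), and so were the receptor PYL4 (AT2G38310, 2.19, SE 0.258), the dehydrin RAB18 (AT5G66400, 2.38, SE 0.195), and the phosphatases ABI1 (1.23) and HAI1 (1.51, adjusted p = 0.0116). NCED3 was at -0.12, AAO3 at 0.23, CYP707A3 at 0.75, BGLU18 at -0.17 and RD29B at 0.07, none past the test. Of the list of ABA receptors 6 were higher and 1 lower of 9 (median 0.72, adjusted p = 0.189), and of the clade A PP2C phosphatases 5 and 1 of 8 (0.75, 0.189). ABA biosynthesis had 4 and 2 of 10 (0.35, 0.831), catabolism 2 and 0 of 6 (0.40, 0.616) and the signalling kinases 4 and 3 of 12 (-0.12, 0.779). Of the ABA and dehydration list 9 were higher and 9 lower of 30 (-0.02, 0.628). The remaining lists did not pass either. Cell division had 7 higher and 0 lower of 10 (0.60, 0.167), jasmonate and wounding 2 and 5 of 16 (0.05, 0.331), and rapid stress and touch 3 and 0 of 18 (0.26, 0.614). Heat shock had 2 and 0 of 6 (0.35, 0.392), salicylate 1 and 3 of 12 (-0.24, 0.331) and glucosinolate 6 and 1 of 14 (adjusted p = 0.465). Flavonoid had 6 and 0 of 10 (adjusted p = 0.189), starch, sugar and malate 5 and 7 of 16 (-0.28, 0.331) and clock 9 and 0 of 11 (0.74, 0.119). Median and mean had opposite signs for kinases (mean 0.21), ABA and dehydration (0.10) and jasmonate (-0.09, the direction of its test).

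Among all genes with a symbol and well above background in both tissues, the largest increases were in ABCA4 (AT3G47750, 3.85, SE 0.203), an ABC transporter, PIN5 (AT5G16530, 3.63, SE 0.349), an auxin carrier, GDU5 (AT5G24920, 3.50), a regulator of amino acid export, FUS3 (AT3G26790, 3.48), a transcription factor known from embryos, GORK, and ABCG27 (AT3G52310, 3.42). The largest decrease was in the microRNA gene MIR846 (AT1G61226), 92.2-fold lower (-6.53, SE 0.441). The metacaspase MC9 (AT5G04200, -3.67) came next, then AOC2 (AT3G25770, -3.66, SE 0.369) and AOC1 (AT3G25760, -2.86, SE 0.489), which make a jasmonate precursor, CLPB2 (AT4G14670, -3.50) and D6PK (AT5G55910, -2.79), a kinase of auxin carriers. Not well above background on any leaf array, AT3G30433, AT3G01190 and AT5G34883 (a probe that lists 4 loci) were at least 5.3-fold, 5.26-fold and 4.95-fold higher in guard cells. Normexp background ended these calls (adjusted p = 0.923, 0.952 and 0.891), and also those of MC9 (0.0768), CLPB2 (0.332; as the mean of its probes it was at -1.68), CYP707A1 (0.49), HAI1 (0.42), ABA3 (0.789) and RBCS1A (0.116).

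In all, 8072 genes were higher and 5710 lower of 22885 tested with limma, 60.2% of them called, and 3724 and 2039 changed at least 2-fold. The median of all tested genes was log2 0.117 and 58.6% of the calls were higher. With arrays scaled to their medians these were -0.184 and 36.3% (5107 higher and 8958 lower), so the balance between the directions rests on the scaling. Each of the groups was on a slide and scan day of its own, and slide or day cannot be told apart from tissue here.

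**Figure D1:**
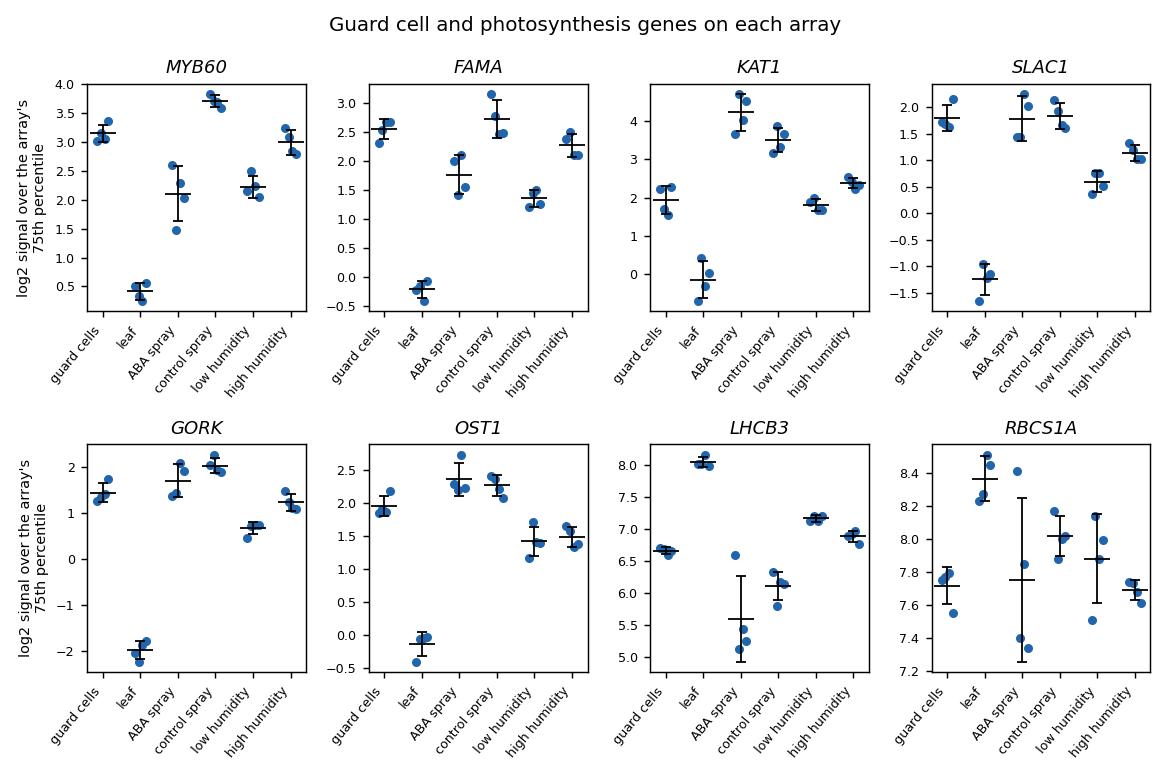
Log2 signal over the array's 75th percentile (vertical axis) of 8 genes on each array of the 6 groups (dots), with group mean (dash) and SD (bars), n = 4. MYB60, FAMA, KAT1, SLAC1, GORK and OST1 were higher in guard cells than in leaf (log2 fold change 2.07 to 3.43) and LHCB3 lower (-1.38). RBCS1A (-0.65) turned to 0.08 with quantile normalization and 0.13 in the value table.

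The second comparison asked how guard cells respond to applied ABA. After 4 h, genes of the hormone's own breakdown and restraint had risen: CYP707A1 (log2 4.05, SE 0.442) and CYP707A3 (AT5G45340, 3.75, SE 0.455), ABA hydroxylases, and the phosphatases HAI1 (AT5G59220, 5.36, SE 0.488) and HAI2 (AT1G07430, 3.56, SE 0.397), which hold ABA signalling down. Of 30 dehydration genes 24 rose (adjusted p = 0.0812 with an estimated correlation), and so did GEA6 (AT2G40170, 5.64, SE 0.652), which encodes a late embryogenesis protein. XTH31 (AT3G44990), a cell wall enzyme that acts on xyloglucan, was 21.6-fold lower (-4.43, SE 0.349). MYB60 fell by log2 1.60 (-1.60, SE 0.172, adjusted p = 9.11e-07) and FAMA was lower too (SE 0.164, adjusted p = 0.000163).

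Of 30 ABA and dehydration genes, 24 rose and 0 fell, 25 and 0 adjusted over the list alone (median 1.45, adjusted p = 1.47e-17). The list had adjusted p = 0.0812 with an estimated correlation. TSPO (AT2G47770, 4.83, SE 0.497), AFP1 (AT1G69260, 4.08, SE 0.307, and 2.67 as the mean of its 2 probes, 1.26 and 4.08), a negative regulator of ABA signalling, and NAC055 (AT3G15500, 3.63) led, and RD29B (AT5G52300, 3.41, SE 0.455) and RAB18 (1.30, SE 0.195) rose. Control replicate 4 stood apart for several of these, and without it HAI1 was at 6.02, TSPO at 5.63 and RD29B at 4.05. Catabolism had 5 higher and 0 lower of 6 (median 2.17, adjusted p = 7.15e-05, and 0.0301 with an estimated correlation), CYP707A4 (AT3G19270, 2.31, SE 0.269, n = 3 ABA arrays) among them and UGT71C5 (-0.07) not called. Of the 9 clade A PP2C phosphatases, 7 rose and 0 fell (median 1.37, adjusted p = 5.16e-07), HAB1 (AT1G72770, 2.48, SE 0.188) and ABI1 (0.82, SE 0.153) included. These had adjusted p = 0.139 with an estimated correlation. Of the receptors 6 of 11 were lower and 1 higher, and 8 and 1 adjusted over the list alone (median -0.41, camera adjusted p = 0.0164, but exact permutation p = 0.429). The receptor list had adjusted p = 0.474 with an estimated correlation and 0.056 with no filter on dim probes. PYL4 (-1.64, SE 0.258), PYL2 (AT2G26040, -1.48, SE 0.225) and PYL6 (AT2G40330, -1.40, SE 0.476, adjusted p = 0.0311) fell and PYL13 rose (1.60, adjusted p = 0.0391, but 0.96 with normexp and 0.14 without control replicate 2). The PYL6 call was lost with replicate as a block (adjusted p = 0.0825), scan date as a block (0.0603) and within scan day 1 (0.0668). It was also lost without ABA replicate 1 (0.0521), ABA replicate 4 (0.0927), control replicate 1 (0.12) or control replicate 2 (0.0516).

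Among 10 ABA biosynthesis genes 3 rose and 1 fell, and the list did not pass (median 0.21, adjusted p = 0.22). NCED3 (AT3G14440), the dioxygenase known from drought, rose by 1.02 (SE 0.205), AAO3, the last oxidase of the pathway, by 0.78 (SE 0.18). ABA1 rose too (SE 0.101, adjusted p = 0.001, but 0.087 with the mean of its probes). NCED5 fell (-1.09, SE 0.353, adjusted p = 0.0237). Its call was lost with replicate as a block (adjusted p = 0.0695), scan date as a block (0.0876) and within scan day 1 (0.0945). The same held without ABA replicate 3 (0.0594), control replicate 1 (0.052) or control replicate 3 (0.0995). Not called were ABA2 (-0.08), ABA3 (0.19, adjusted p = 0.539, but 0.0361 within scan day 1) and BGLU18 (-0.05).

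Guard cell genes moved both ways, 4 higher and 9 lower of 20, also adjusted over the list alone, with the list lower (median -0.38, adjusted p = 0.00484, exact permutation p = 0.0286). The list had adjusted p = 0.492 with an estimated correlation. Beside MYB60 and FAMA, AT1G22690 (-2.43, SE 0.333) and the myrosinase TGG1 (AT5G26000, -1.43, SE 0.194) fell, whereas SLAH3 (0.91), ALMT12 (0.52), CYP86A2 (0.42) and KAT1 (adjusted p = 0.0265) rose. The call of ALMT12 (adjusted p = 0.0423) was lost without any of 6 of the 8 arrays, with 0.33 (adjusted p = 0.17) without ABA replicate 3, and CYP86A2 was not called as the mean of its probes (0.15, adjusted p = 0.419). KAT1 lost its call without ABA replicate 2 (0.103) or 4 (0.079) or control replicate 1 (0.0784) or 3 (0.0731). OST1 (adjusted p = 0.647), SLAC1 (adjusted p = 0.882) and GORK (-0.32, adjusted p = 0.131, but 0.0327 without ABA replicate 3) were not called. Stomatal lineage genes fell, 4 lower and 0 higher of 12, 5 and 0 adjusted over the list alone (median -0.63, adjusted p = 0.00125, exact permutation p = 0.0571). The median was -0.96 without ABA replicate 1, and the list had adjusted p = 0.492 with an estimated correlation. The peptide EPF1 (AT2G20875, -2.46, SE 0.315) and the receptor kinases ERL2 (AT5G07180, -1.76, SE 0.183) and ER (AT2G26330, -1.15, SE 0.16) fell most.

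Markers of other cells moved with the spray. Mesophyll genes were lower, 7 of 18 and 0 higher, 10 and 0 adjusted over the list alone (median -0.38, adjusted p = 0.00125, exact permutation p = 0.143). The median was -0.58 without ABA replicate 1, and the list had adjusted p = 0.504 with an estimated correlation. CA2 (AT5G14740, -1.12, SE 0.208), CA1 (-0.74, SE 0.207) and PRK (-0.59, adjusted p = 0.0281) fell. PRK lost its call without ABA replicate 2 (0.112) or 4 (0.119) or control replicate 1 (0.0672) or 3 (0.0687). LHCB3 (-0.51, adjusted p = 0.0684) passed with replicate as a block (0.0335), with scan date as a block (-0.92, 0.00127), and without ABA replicate 1 (3.03e-06) or control replicate 2 (0.0453). RBCS1A (-0.27, adjusted p = 0.281) passed with quantile normalization (0.0478), with scan date as a block (-0.65, 0.00321) and without ABA replicate 1 (0.00893). Epidermis and cuticle genes were higher, 8 of 22 and 4 lower, 10 and 4 adjusted over the list alone (median 0.35, adjusted p = 0.0199). It had adjusted p = 0.504 with an estimated correlation. The wax genes CER1 (AT1G02205, 3.73, SE 0.323), WSD1 (AT5G37300, 3.20, SE 0.416) and MAH1 (AT1G57750, at least 2.28-fold, adjusted p = 0.0109, and 0.0543 without control replicate 3) rose, though with normexp background MAH1 turned to -0.11 and its bound did not hold. LACS2 (-0.64), LCR (-1.04), GPAT8 (-1.29) and PDF2 (-1.01) fell. That list lost its call with scan date as a block (median 0.12, adjusted p = 0.687), and within scan day 1 (0.653), and also without ABA replicate 1 (0.0811) or ABA replicate 3 (0.121). Trichome genes had 0 higher and 5 lower of 11 (-0.51, adjusted p = 0.0858). They passed with replicate as a block (0.0318) and without ABA replicate 1 (0.0458).

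Rapid stress and touch genes rose, 10 of 18 and 0 lower (median 0.78, adjusted p = 0.00129). With an estimated correlation it had adjusted p = 0.504. The regulators WRKY40 (AT1G80840, 2.39, SE 0.519) and WRKY53 (AT4G23810, 2.24, SE 0.244) and the touch gene TCH4 (AT5G57560, 1.72, SE 0.592, adjusted p = 0.0333) led. The TCH4 call was lost with replicate as a block (0.06), scan date as a block (0.0736) and within scan day 1 (0.0812). It was lost as well without ABA replicate 2 (0.0567), 3 (0.0627) or 4 (0.0738) or control replicate 2 (0.0988) or 3 (0.0786). The vasculature list did not pass (3 higher and 1 lower of 14, median -0.05, mean 0.20, adjusted p = 0.582), though the sugar exporters SWEET12 (2.90) and SWEET11 (1.16) rose. Nor did ion transport (4 and 8 of 27, -0.06, 0.261), kinases (3 and 2 of 12, 0.07, 0.582, with the receptor kinase GHR1 at -1.97, or -0.87 as the mean of its probes) or starch (3 and 6 of 16, -0.09, mean 0.12, 0.582). Jasmonate had 1 higher and 0 lower of 16 (0.56, 0.171, but 0.042 without control replicate 4), with JAZ1 at 1.36 (adjusted p = 0.0281, and 0.109 without control replicate 1). The others that did not pass were cell division (0 and 2 of 10, -0.32, 0.151), heat shock (0 and 0 of 8, adjusted p = 0.582) and salicylate (0 and 1 of 12, -0.06, 0.756), and also glucosinolate (0 and 2 of 14, -0.05, 0.582), flavonoid (0 and 0 of 11, -0.08, 0.582) and clock (1 and 1 of 11, adjusted p = 0.791). The tests went with the mean for vasculature and with the median for starch.

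By the same rule, the largest increases were in UGT74E2 (AT1G05680), a glucosyltransferase that acts on an auxin, 56.1-fold higher (5.81, SE 0.339), GEA6, HAI1, GSTU9 (AT5G62480, 5.35, SE 0.315), a glutathione transferase, LEA7 (AT1G52690, 5.28, and 6.18 without control replicate 4) and LBD1 (AT1G07900, 5.18). The largest decreases were in XTH31 and the expansins EXPA8 (AT2G40610, -4.20, SE 0.643, and -5.21 without ABA replicate 1), EXPA5 (AT3G29030, -3.17, SE 0.254) and EXPB3 (AT4G28250, -2.57, SE 0.374). Others were in CKX4 (AT4G29740, -2.92), a cytokinin oxidase, and SAUR26 (AT3G03850, -2.84). Not well above background on any control array, AT3G49540, NAC095 (AT5G41090) and AT2G23270 were at least 5.31-fold, 3.96-fold and 3.5-fold higher. For AT3G49540 the bound was 8.74-fold without ABA replicate 3 and 3.47-fold without ABA replicate 4, and for AT2G23270 it was 5.29-fold without ABA replicate 3. On no ABA array well above background, MIR169e (AT1G53687), AT3G19610 and CHX4 (AT3G44900) were at least 1.72-fold, 1.68-fold and 1.4-fold lower. AT3G19610 lost its call without ABA replicate 2 (adjusted p = 0.0954). With normexp background none of these 6 was called (adjusted p = 0.916 to 0.981), nor were CA1 (0.0698), PRK (0.325), PYL6 (0.607), NCED3 (0.195) and NCED5 (0.615).

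In all, 3428 genes were higher and 4017 lower of 25349 tested with limma (29.4%), 1427 and 596 by at least 2-fold. With scan date as a block the counts were 3763 and 3727, and within scan day 1, where 2 ABA arrays stand against the 4 controls, 3871 and 3822. All lists called above except epidermis and cuticle kept their call in both. These settings are not separate checks, since both take the ABA effect from ABA replicates 2 and 4 alone. Within ABA, scan date and slide cannot be told apart. With scan date as a block medians were -0.57 for guard cell genes, -0.97 for stomatal lineage, -0.67 for mesophyll, -0.47 for receptors, 1.93 for phosphatases, 1.42 for ABA and dehydration and 0.97 for rapid stress. Slide as a random block left 1877 higher and 1437 lower. No slide held both ABA and control arrays, so slide cannot be told apart from the spray.

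**Figure D2:**
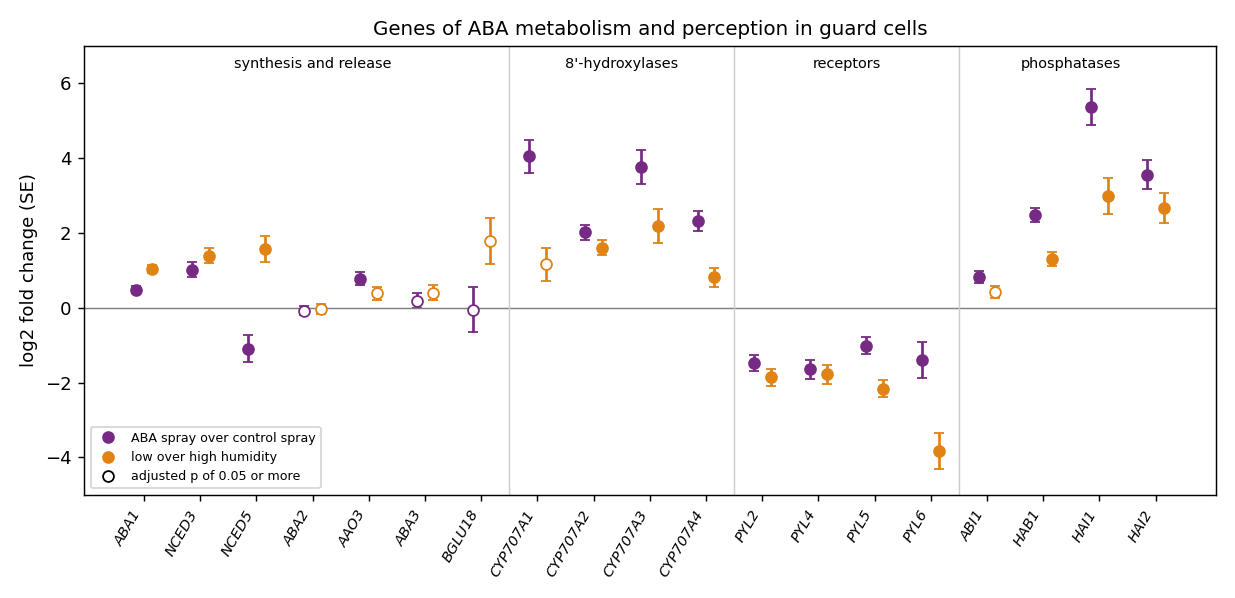
Log2 fold change (vertical axis) with standard error (bars) of 19 genes of ABA synthesis, breakdown and perception, for ABA spray over control spray (purple) and low over high humidity (orange), n = 4 arrays per group, and open symbols for an adjusted p of 0.05 or more. CYP707A1 was at 4.05 with ABA and 1.16 in dry air, and NCED5 at -1.09 and 1.58.

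The third comparison asked how guard cells respond to dry air. Of the ABA synthesis genes 3 of 9 rose: NCED3 by log2 1.39 (SE 0.205), NCED5 by 1.58 (SE 0.353) and ABA1 by 1.03 (SE 0.101). So did 25 of 30 dehydration genes and 8 of 16 jasmonate genes (adjusted p = 0.148 for jasmonate with an estimated correlation). LTP3 (AT5G59320), a lipid transfer protein, was 16.9-fold higher (4.08, SE 0.519, adjusted p = 3.02e-05). Lower were the receptor PYL6 (-3.83, SE 0.476) and the channel ALMT12 (-1.58, SE 0.188), as were all 4 transcription factor genes of the iron deficiency response around bHLH38 (AT3G56970, -2.97, SE 0.714).

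Of the 30 ABA and dehydration genes, 25 rose and 0 fell, 27 and 0 adjusted over the list alone (median 1.54, adjusted p = 8.65e-30, and 0.0185 with an estimated correlation). Among them were LEA4-5 (AT5G06760, 3.73, SE 0.447, well above background on 2 high humidity arrays), RD20 (AT2G33380, 3.22, SE 0.268), a caleosin, AFP1 (2.97, SE 0.307) and RAB18 (0.93, SE 0.195). The 4 RAB18 probes ranged from -0.88 to 0.97, and their mean was not called (0.46, adjusted p = 0.0874). RD29B was at 1.15 (adjusted p = 0.108). ABA biosynthesis had 3 higher and 0 lower of 9, 4 and 0 adjusted over the list alone (median 0.41, adjusted p = 0.000138, and 0.0185 with an estimated correlation). Not called were ABA2 (-0.03), ABA3 (0.41), AAO3 (0.38) and BGLU18, which frees ABA from its glucose ester (1.79, adjusted p = 0.0594, but 0.0322 without low humidity replicate 2). Catabolism had 3 higher and 1 lower of 6 (median 0.99, adjusted p = 0.0454). It had adjusted p = 0.148 with an estimated correlation. CYP707A3 (2.17, SE 0.455), CYP707A2 (AT2G29090, 1.61, SE 0.203) and CYP707A4 (SE 0.249, adjusted p = 0.0369) rose. UGT71C5 fell (-0.53), and CYP707A1 was at 1.16 (adjusted p = 0.0946). The list lost its call without low humidity replicate 4 (0.0605) or high humidity replicate 1 (0.0884), with normexp (0.0885) and with only the compared arrays (0.0577). CYP707A4 lost its call without low humidity replicate 1 (0.09), 2 (0.0672), 3 (0.059) or 4 (0.0779) or high humidity replicate 2 (0.0987) or 3 (0.106).

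Receptors fell, 6 of 9 lower and 1 higher, 7 and 1 adjusted over the list alone (adjusted p = 1.62e-06, and 0.0304 with an estimated correlation). PYL6, PYL5 (AT5G05440, -2.16, SE 0.23), PYL2 (-1.86, SE 0.225) and PYL4 (-1.78, SE 0.258) fell and PYL7 rose (0.38, adjusted p = 0.0324, but 0.0922 without high humidity replicate 4). Of 8 clade A PP2C phosphatases, 6 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.92, adjusted p = 8.23e-07). They had adjusted p = 0.0785 with an estimated correlation. HAI1 was 7.92-fold (adjusted p = 0.000364) and HAI2 6.39-fold higher (adjusted p = 0.000149), with log2 SE of 0.488 and 0.397, and HAB1 was at 1.31 (SE 0.188). ABI1 was at 0.42 (adjusted p = 0.084).

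Of the 20 guard cell genes 11 fell and 0 rose, 13 and 0 adjusted over the list alone (median -0.57, adjusted p = 2.3e-07, exact permutation p = 0.0286). The list had adjusted p = 0.0785 with an estimated correlation. AT1G22690 (-2.66, SE 0.333), ALMT12, the proton pump AHA5 (AT2G24520, SE 0.089, adjusted p = 2.17e-07), FAMA (-0.92, SE 0.164), MYB60 (-0.77, SE 0.172) and GORK (-0.56, SE 0.155, adjusted p = 0.0205) fell. GORK lost its call without high humidity replicate 1 (0.074) or low humidity replicate 1 (0.0705). SLAC1 (-0.54, adjusted p = 0.0701), KAT1 (adjusted p = 0.129) and OST1 (-0.07) were not called. Mesophyll genes stood on the other side of 0, 1 higher and 0 lower of 18 (median 0.14, adjusted p = 0.0506, exact permutation p = 0.0571), with LHCB3 at 0.28 and RBCS1A at 0.19, neither called. That list passed without low humidity replicate 1 (0.0131), high humidity replicate 2 (0.0248) or high humidity replicate 3 (0.0451). Ion transport had 2 higher and 8 lower of 27, 3 and 11 adjusted over the list alone (median -0.20, adjusted p = 0.0113). It had adjusted p = 0.0999 with an estimated correlation. ABCB14 (AT1G28010), a malate importer of guard cells, fell (-0.97, SE 0.2), and NHX2 (0.78) and PIP2;1 (1.19) rose.

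Jasmonate and wounding genes rose, 8 of 16 and 0 lower, 12 and 0 adjusted over the list alone (median 1.64, adjusted p = 1.77e-07). The list had adjusted p = 0.148 with an estimated correlation. Its members included the jasmonate repressors JAZ8 (AT1G30135, SE 0.642, adjusted p = 0.0299) and JAZ1 (AT1G19180, 1.88, SE 0.454) and the synthesis gene AOC1 (SE 0.489, adjusted p = 0.0114). The JAZ8 call was lost without high humidity replicate 1 (0.0744), 2 (0.0687) or 4 (0.0582) or low humidity replicate 2 (0.0545), 3 (0.101) or 4 (0.0665). Rapid stress and touch had 8 higher and 0 lower of 18, 13 and 0 adjusted over the list alone (median 1.03, adjusted p = 2.3e-07), and adjusted p = 0.148 with an estimated correlation. The transcription factors RRTF1 (AT4G34410, 3.58, SE 0.851) and WRKY40 (2.52, SE 0.519) and the zinc finger gene SZF1 (AT3G55980, 1.47, SE 0.291) rose. Glucosinolate genes rose, 6 of 14 and 0 lower, 7 and 1 adjusted over the list alone (median 0.55, adjusted p = 0.000578). They had adjusted p = 0.0785 with an estimated correlation and 0.057 with normexp. Higher were CYP79F1 (AT1G16410, 1.55, SE 0.188) and CYP79F2 (AT1G16400, 1.22, SE 0.265), which start their synthesis from methionine, and MAM1 (AT5G23010, 0.87, SE 0.157). In starch, sugar and malate metabolism 4 rose and 2 fell of 16, 6 and 3 adjusted over the list alone (adjusted p = 0.0151). That list had adjusted p = 0.19 with an estimated correlation and 0.397 with normexp. The sucrose synthases SUS3 (AT4G02280, 1.75, SE 0.217) and SUS1 (AT5G20830, 1.18, SE 0.201) and the amylase BAM1 (AT3G23920, 0.94, SE 0.127) rose, and PWD (-0.40) and PCK1 fell. Without low humidity replicate 2 PWD (adjusted p = 0.123), and without replicate 1 PCK1 (0.138), lost the call.

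Epidermis genes did not pass as a list (5 higher and 5 lower of 20, median 0.03, mean 0.23, test direction down, adjusted p = 0.989), though WSD1 (3.34) and CER1 (1.69) rose. Others that did not pass were stomatal lineage (0 and 0 of 12, -0.13, 0.485), trichome (0 and 0 of 12, -0.08, 0.742), vasculature (0 and 1 of 14, -0.02, 0.606), cell division (0 and 0 of 10, 0.02, 0.989) and kinases (0 and 1 of 12, -0.05, 0.47). Heat shock had 1 higher and 0 lower of 6 (0.05, 0.989), the chaperone BIP3 (2.81). Salicylate and defence genes had 2 and 1 of 12 (0.29, 0.228), the pathogenesis proteins PR2 (2.14) and PR5 (1.93) higher and EDS1 (-0.71) lower. Of the flavonoid list 3 were higher and 2 lower of 10 (0.12, 0.742), chalcone synthase CHS at 2.98 and TT7 at -1.39 among them. The clock list had 2 and 1 of 11 (-0.35, 0.989), LHY (1.52) higher and LUX (-1.15) lower. Calls lost without 1 array were those of PR2 (adjusted p = 0.0984) and LUX (0.0886) without low humidity replicate 1 and EDS1 (0.109) without high humidity replicate 2, and BIP3 was not called with normexp (0.0774).

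By that rule the largest increases were in LTP3, BAM5 (AT4G15210, 3.86, SE 0.851), a beta-amylase, ATGA2OX1 (AT1G78440, 3.78, SE 0.418), which inactivates gibberellins, RRTF1, PUB19 (AT1G60190, 3.56), a ubiquitin ligase, and EXPA16 (AT3G55500, 3.46, SE 0.316). The largest decreases were in PYL6, BHLH100 (AT2G41240, -3.66, SE 0.952), bHLH39 (AT3G56980, -3.45, SE 0.776), bHLH38, BHLH101 (AT5G04150, -2.92, SE 0.551) and SOS3 (AT5G24270, -2.57, SE 0.198), a calcium sensor. BHLH100 lost its call without low humidity replicate 3 (-3.17, SE 1.013, adjusted p = 0.0536), and with normexp PYL6 (0.413), bHLH38 (0.35), bHLH39 (0.558) and BHLH101 (0.236) lost theirs. On no high humidity array well above background, AT3G42052 (adjusted p = 0.0546 with only the compared arrays), AT1G24996 (a probe that lists 3 loci, adjusted p = 0.0915 with those arrays) and LEA18 (AT2G35300) were at least 8.89-fold, 3.66-fold and 2.61-fold higher. AT3G42052 and AT1G24996 rest on low humidity replicate 1, where they were at 0.07 and -1.49 (the other 3 arrays at -4.82 or below and -6 or below). Both are among the genes that part gl1-1 from Col-0, and AT3G42052 was at 2.41 as the mean of its probes. Without that array the bounds were 3.19-fold and 1.4-fold, and neither gene was bright enough to be tested. On no low humidity array well above background, AT4G26820, AT5G58784 and AT2G25770 were at least 8.94-fold, 6.54-fold and 3.63-fold lower. With normexp background these bounds did not hold, since the genes turned (0.00, 0.23 and 0.57) and AT3G42052, AT1G24996 and LEA18 lost their calls (0.366, 0.541 and 0.584). So did NCED5 (0.458), CYP707A4 (0.215), ABCB14 (0.31), JAZ8 (0.174), CYP79F2 (0.368), MAM1 (0.0755), GORK (0.228) and RAB18 (0.0536). With capped local backgrounds no named gene turned.

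In all, 1487 genes were higher and 1324 lower of 22185 tested with limma (12.7%), 590 and 266 by at least 2-fold. Without low humidity replicate 1, the array with transcripts of the gl1-1 arrays, 1222 were higher and 943 lower. NCED3 was then at 1.38, LTP3 at 3.96 and PYL6 at -3.92, and all lists called above kept their calls. Of the 74 genes that part the lines, 33 were tested in dry air and 10 called higher, against 3 without that array. The low and the high humidity arrays were on a slide each, which cannot be told apart from the treatment, and were scanned on the same day.

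**Figure D3:**
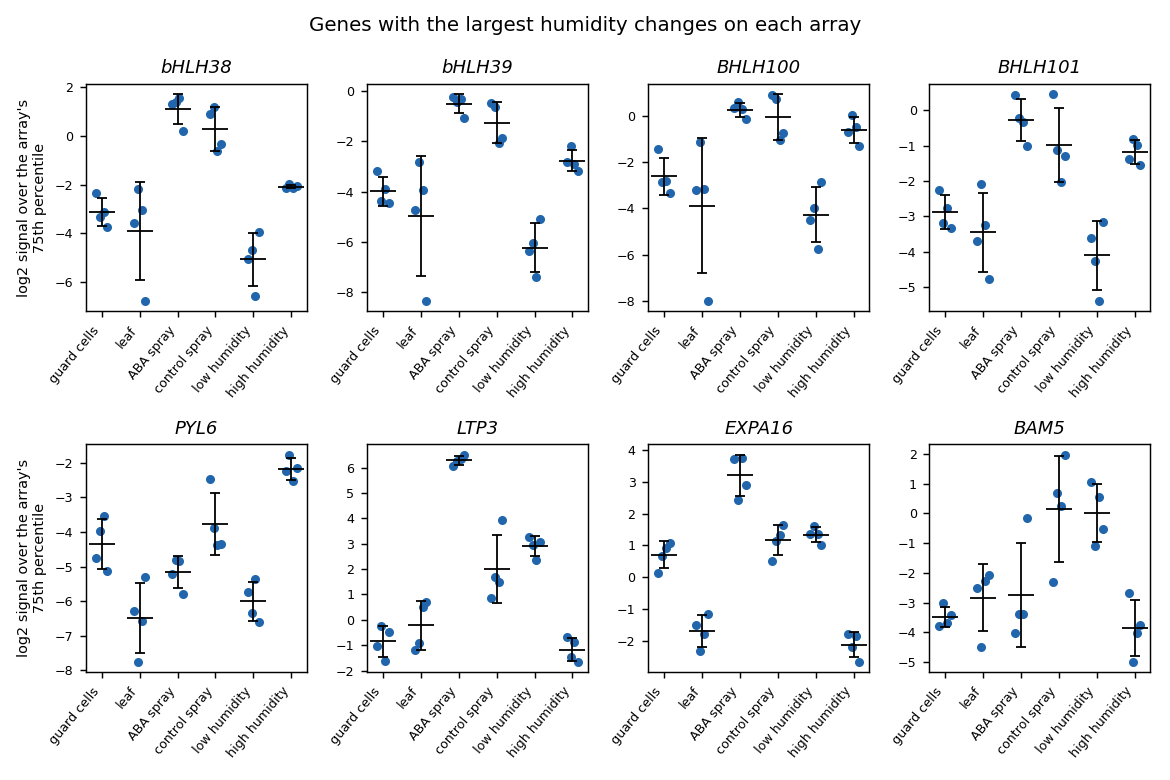
Log2 signal over the array's 75th percentile (vertical axis) of bHLH38, bHLH39, BHLH100, BHLH101, PYL6, LTP3, EXPA16 and BAM5 on each array of the 6 groups (dots), with group mean (dash) and SD (bars), n = 4. The 4 bHLH genes and PYL6 were lower at low than at high humidity (log2 fold change -2.92 to -3.83) and the others higher (3.46 to 4.08).

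**Figure D4:**
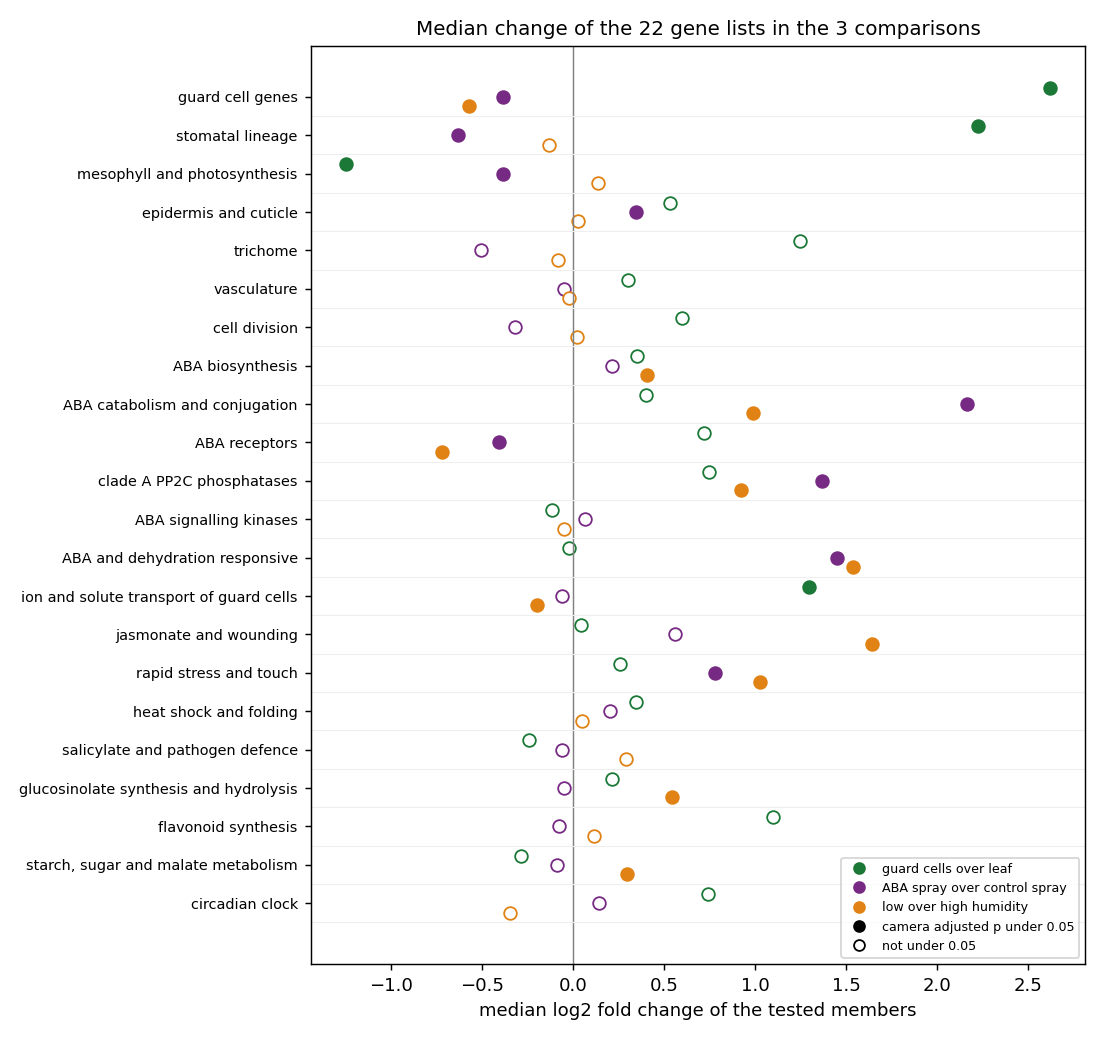
Median log2 fold change (horizontal axis) of the 22 gene lists in the comparisons of tissue, ABA spray and humidity, where filled symbols have a camera adjusted p under 0.05 and open symbols do not. ABA and dehydration genes were at 1.45 with ABA and 1.54 in dry air, and guard cell genes at 2.62 over leaf, -0.38 with ABA and -0.57 in dry air.

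How alike the responses to ABA and to dry air were was asked last. With ABA and in dry air, 24 and 25 of 30 dehydration genes rose, as did 7 of 9 and 6 of 8 phosphatases, and 6 of 11 and 6 of 9 receptors fell. With an estimated correlation the adjusted p was 0.0812 and 0.0185 for dehydration genes, 0.139 and 0.0785 for phosphatases and 0.474 and 0.0304 for receptors. The ABA synthesis gene NCED5 and the anion channel ALMT12 differed between the treatments (ABA effect minus humidity effect -2.67, adjusted p = 0.00101, for NCED5, and adjusted p = 2.61e-05 for ALMT12). That they moved in opposite directions is not established: ALMT12 with ABA was at 0.52 (adjusted p = 0.0423), and at 0.33 (0.17) without ABA replicate 3. The fall of NCED5 with ABA was not called with replicate as a block (adjusted p = 0.0695), scan date as a block (0.0876) or within scan day 1 (0.0945). CYP707A1 differed by 2.89 (adjusted p = 0.00324) and PYL6 by 2.43 (adjusted p = 0.0169). The differences were widest for the glucosyltransferase UGT74E2 (5.46, SE 0.479) and the amylase BAM5 (-6.74, SE 1.204, and -7.60 without ABA replicate 4 or -7.57 without control replicate 1).

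Of the genes tested in both, 647 were higher in both against 220.8 for independent calls (odds ratio 5.27, one-sided Fisher's exact p = 1.11e-170) and 444 lower in both against 239.8 (odds ratio 2.45, p = 3.02e-44, same test). Another 159 were higher with ABA and lower in dry air (odds ratio 0.775) and 157 the reverse (0.512). Fold changes correlated across 25586 genes at Pearson r = 0.307 and Spearman rho = 0.233. Genes are not independent replicates, and leaving out arrays gave r a jackknife SE of 0.07. With the ABA groups kept and the humidity arrays split in all 35 ways, 5 splits gave a correlation at least as large in size (highest other 0.35). No array is shared between the effects, but ABA was sprayed on gl1-1 and humidity was changed on Col-0, so genotype and treatment change together. Without low humidity replicate 1 the correlation was 0.316, 887 genes were called in both in the same direction, and 3823 differed.

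The effects differed for 4304 of 25586 genes, 2174 with a larger value for ABA and 2130 with a smaller one, 1084 and 611 by at least 2-fold. With the ABA groups kept, 11 of 70 groupings of the humidity arrays gave as many (highest other 6625, the humidity groups exchanged). The size of this count thus follows the ABA effect. Regrouping does not set the effects equal, so it cannot test whether the treatments differ. Beside UGT74E2, the ABA effect was higher most for GSTU9 (5.36, SE 0.446), DIN10 (AT5G20250, 4.30, SE 0.504), CSLG2 (AT4G24000, SE 0.857, adjusted p = 0.0019, at 5.18 without control replicate 4) and the cytochrome CYP81D8 (AT4G37370, 4.23, SE 0.502). As the mean of its probes DIN10 was at 1.45 and not called (adjusted p = 0.0965). The ABA effect was lower most for BAM5, ATGA2OX1 (-5.23, SE 0.591), the aquaporin RD28 (AT2G37180, -4.78, SE 0.387), XTH31 (SE 0.493, adjusted p = 4.63e-06) and DDF1 (AT1G12610, -3.67, SE 0.935). With normexp CSLG2 (adjusted p = 0.079) and DDF1 (0.0993) were not called.

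Of the 22 lists 8 differed by camera with its preset correlation. With an estimated correlation camera called 0, with 2 at an unadjusted p under 0.05, and fry called 8. Higher with ABA were catabolism (4 and 0 of 6 higher and lower, median difference 1.54, adjusted p = 0.00249, adjusted p = 0.142 with an estimated correlation) and clade A PP2C phosphatases (4 and 0 of 9, 0.79, 0.0151, adjusted p = 0.591 with an estimated correlation). So was epidermis (8 and 1 of 22, 0.49, 0.0313, adjusted p = 0.67 with an estimated correlation), with HAI1 at 2.38, HAB1 at 1.17 and CER1 at 2.04 by gene. Lower with ABA were glucosinolate (0 and 5 of 14, -0.75, 0.00249, adjusted p = 0.206 with an estimated correlation) and mesophyll (0 and 4 of 18, -0.55, 8.21e-05, adjusted p = 0.591 with an estimated correlation). Stomatal lineage (0 and 3 of 12, -0.53, 0.0151, adjusted p = 0.67 with an estimated correlation) was lower too. The remaining lower lists were jasmonate (0 and 2 of 16, -0.85, 0.0313, adjusted p = 0.674 with an estimated correlation) and starch (1 and 4 of 16, -0.20, 0.0388, adjusted p = 0.591 with an estimated correlation), with CYP79F1 at -1.43 (n = 3 ABA arrays) and EPF1 at -1.50. With scan date as a block epidermis (0.652), jasmonate (0.305) and starch (0.0759) lost their calls. Lists whose difference did not pass included ABA and dehydration (median 0.27, adjusted p = 0.446), guard cell genes (0.19, 0.453), receptors (0.38, 0.255), biosynthesis (-0.20, 0.255) and rapid stress (-0.04, 0.754). Members that differed were RD29B (2.25, adjusted p = 0.02) and TSPO (3.64, adjusted p = 0.00135), while NCED3 did not (-0.37, adjusted p = 0.443).

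With an estimated correlation in place of the preset one, the list calls that held were ion transport in guard cells over leaf, catabolism with ABA, and ABA biosynthesis, receptors and ABA and dehydration genes in dry air. The exact permutation p of the array means was 0.0286 for every list called in guard cells over leaf and in dry air. With ABA it was 0.0286 too, except for stomatal lineage (0.0571), mesophyll (0.143) and receptors (0.429). These assignments ignore that the numbers may pair ABA and control samples. Within the pairs the differences had 1 sign in 8 of the 9 called lists (all but receptors) and in 3 of the 13 others (jasmonate, ABA biosynthesis and glucosinolate). A paired test of 4 pairs cannot give a p below 0.125. By fry, 16, 13 and 12 of the 22 lists moved on balance in 1 direction in the 3 comparisons, where camera called 4, 9 and 11.

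**Figure D5:**
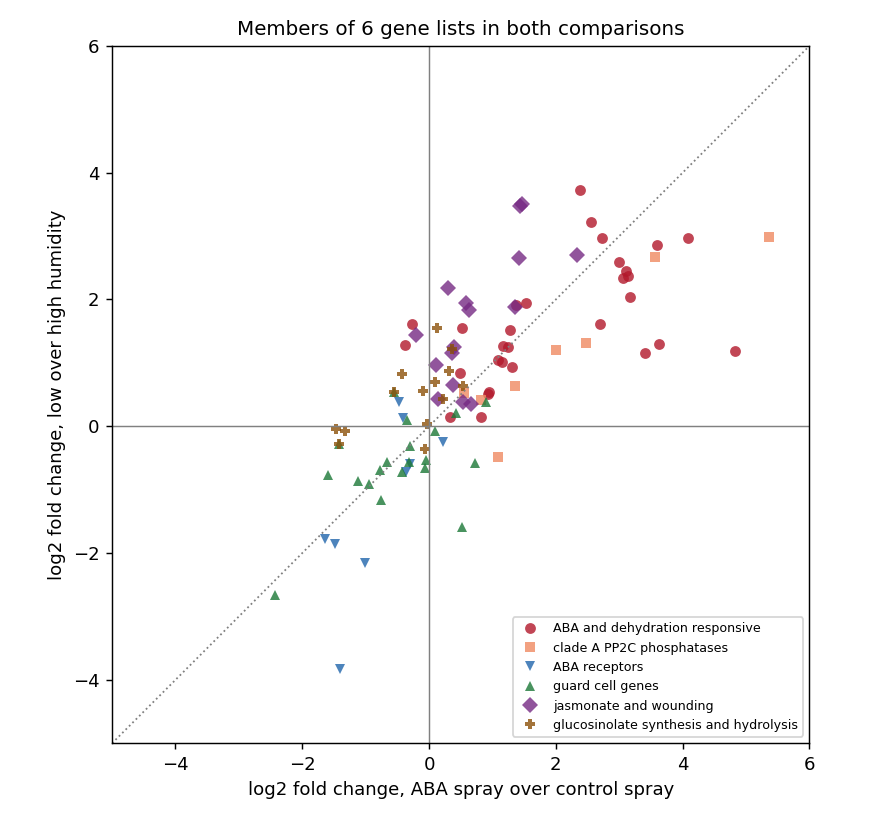
Log2 fold change with ABA spray (horizontal axis) against low over high humidity (vertical axis) for the members of 6 lists (1 dot per gene), where the dotted line marks equal change. Dehydration genes (medians 1.45 and 1.54) lie in the upper right and receptors such as PYL4 (-1.64 and -1.78) in the lower left.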

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

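Of the tests in this part, those of the genes lower in guard cells over leaf, of the slides of the humidity groups, of the drawn groupings that part the numbered pairs, of the humidity groupings with the ABA groups kept, of the other iron deficiency genes as a list, of the lower values of the bHLH38 group without 1 array and of the gl1-1 transcripts were chosen only after the result was seen.

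Arrays that stood apart from the other 3 of their group by Dixon's test were found in 24 of 288 groups of values, where chance alone gives about 1 in 20, or 14.4. In the share of probes well above background these were guard cells replicate 4 (91.54%, others 77.41 to 79.67%), ABA replicate 4 (92.1%, others 85.29 to 86.33%) and high humidity replicate 2 (71.55%, others 77.43 to 78.57%). The spike-in slope of high humidity replicate 1 was 0.927 (others 0.909 to 0.911). In array means of lists (log2), guard cells replicate 4 was at -2.773 for ABA receptors (others -3.601 to -3.551), replicate 3 at -1.721 for jasmonate (others -1.482 to -1.46) and replicate 2 at -0.391 for salicylate (others -1.252 to -1.132). ABA replicate 1 was at 0.037 for ABA catabolism (others 0.559 to 0.597), ABA replicate 2 at -0.019 for kinases (others 0.078 to 0.093) and control replicate 2 at -0.242 for salicylate (others -0.561 to -0.544). Low humidity replicate 1 was at 5.657 for mesophyll (others 5.818 to 5.847), replicate 3 at -1.98 for cell division (others -2.534 to -2.462) and at -3.026 for flavonoid synthesis (others -3.342 to -3.298), and replicate 4 at -0.176 for kinases (others -0.093 to -0.08). High humidity replicate 1 was at -1.5 for PP2C phosphatases (others -1.711 to -1.68).

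Single genes with 1 array far from the rest (log2 over the array's 75th percentile) were OST1 in guard cells replicate 4 (2.19, others 1.86 to 1.91) and leaf replicate 1 (-0.41, others -0.07 to -0.03), RBCS1A in guard cells replicate 4 (7.55, others 7.75 to 7.79) and GORK in low humidity replicate 1 (0.46, others 0.71 to 0.74). NCED3 was at -1.71 in ABA replicate 1 (others -1.3 to -1.26), ABI1 at 4.37 in control replicate 2 (others 4.14 to 4.17) and GL1 at -8.42 on the same array (others -7 to -6.86). In high humidity, ABA3 was at -3.37 in replicate 3 (others -2.53 to -2.47) and BGLU18 at 1.99 in replicate 2 (others 3.97 to 4.26). Probes without a locus, which no comparison of genes used, also passed the test: 1799 of 3476 for guard cells over leaf (1087 higher and 712 lower), 681 of 3910 with ABA (399 and 282) and 271 of 3154 in dry air (176 and 95). Pseudogene loci were higher in guard cells over leaf (708 loci, median log2 0.352, and 0.206 without guard cells replicate 4), by no more than coding loci of the same mean signal (excess -0.078). In high humidity guard cells over the same leaf arrays they were at 0.182 (0.023 to 0.308 by array), in control spray guard cells at 0.995, and no cause is put forward.

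The number of genes called was set against other groupings of the same arrays. For guard cells over leaf 1 of 35 splits, the real one, gave as many genes (13782, highest other 959), and for humidity 1 of 35 (2811, highest other 0). A share of 1 of 35 is the smallest these splits can give, so it argues against chance for both without excluding it. That holds only if these samples are not paired, and pairing by the numbers in their titles was not checked. Slide parts these arrays as the real split does, so a difference between slides would give the same. For ABA, too, 1 of 35 splits gave as many genes (7445, highest other 2608, a split of ABA replicate 1 and controls 1 to 3 against the rest). The numbers may pair these samples, and the 8 splits that part all 4 numbered pairs (highest other 893) are too few for a share under 0.05. Of 100 drawn groupings of the ABA and humidity arrays, 1 gave as many genes with different effects (4304, highest other 3255), 1 as many genes called in both in the same direction (1091, highest other 0), and 3 a correlation as large (0.307, highest other 0.343). Of 100 drawn only from groupings that part those pairs, these numbers were 3 (highest other 4367), 1 (highest other 32) and 3 (highest other 0.35). With the real ABA groups kept, 11 of 70 groupings of the humidity arrays gave as many genes with different effects (highest other 6625), 1 of 70 as many called in both (highest other 316, both with the humidity groups exchanged) and 5 of 35 a correlation as large (highest other 0.35). The first count follows the ABA split whatever the humidity split, so drawing over both was the wrong bound for it and for the correlation. The number called in both was fixed by the humidity split, since every other split called 0 genes in dry air. Only the real humidity groups and their exchange could share calls with ABA. These groupings thus do not test the shared direction, and they do not set the effects equal. Chance cannot be told apart by them for any of these measures.

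Guard cell genes were lower in dry air (11 of 20, median log2 -0.57). A lower share of guard cells in the dry samples would lower other guard cell transcripts alike. The 924 other genes at least 4-fold higher in guard cells over leaf had a median of 0.02 (exact permutation p = 0.6). This argues against a lower share as the source of the whole fall. Yet 52 of these genes were called higher and 122 lower, against 1487 and 1324 of all 22185 tested. Their calls thus lean the way of a lower share. Scaling is argued against as well, since the highest adjusted p of the list over 4 other settings was 3.09e-07. The 1771 genes at least 2-fold lower in guard cells over leaf had a median of 0.116 (243 higher and 23 lower, exact permutation p = 0.0286), so some shift of cell types stays open. With 0 slides that hold both humidity groups, slide and treatment cannot be told apart, and a response of guard cells to dry air stays open beside it.

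Low humidity replicate 1 carried transcripts that part the gl1-1 from the other Col-0 arrays, although its label gives Col-0 (74 genes, median share of the gl1-1 signal 0.454). All gl1-1 arrays were sprayed, so line and spray cannot be told apart in the choice of these genes. A whole gl1-1 sample under this label is argued against, since the upper quartile of the share was 0.576. The share was at most 0.018 on the other 3 low humidity arrays, but this cannot test a response to dry air. The genes were chosen as far lower on the other Col-0 arrays, low humidity arrays included, so a low share there was largely fixed beforehand. A candidate explanation is gl1-1 material mixed into this sample, at the share of 0.454, a value seen before that test was written. By gene the share ran from -0.063 (TOC75-IV) to 1.069 (AT1G15885), so 0.454 does not describe all of them. At which step such material came in, and whether plants of mixed descent would give the same, stays open.

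The genes of the bHLH38 group were lower in dry air (log2 -2.92 to -3.66, median -3.212, and -1.869 with capped normexp). A single array as the source of the lower values is argued against, since the highest of the 4 genes without any 1 array was -2.47. BHLH100 alone lost its call, with adjusted p = 0.0536 without low humidity replicate 3 (-3.17, SE 1.013, against -3.66, SE 0.952), where the fold came closer to 0 and its error grew. Whether they are part of a lower iron deficiency response as a whole cannot be told apart: the other iron deficiency genes had a median of -0.529 but did not pass as a list (adjusted p = 0.214, and 0.515 with an estimated correlation), with FRO3 (-2.18), BTS (-1.54) and OPT3 (-0.72) lower, but FRO2 (1.99) and NAS1 (1.30) higher, of 9 tested. Whether dry air changed iron in guard cells, and the slide of each group, stay open.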

How the results depend on the processing

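Of the settings in this part, normexp with capped local backgrounds, arrays of scan day 1 only, 1 background rule for all arrays and leaving out both doubted arrays were chosen after seeing the data. Among counts and the correlation, 203 values under other settings stayed within 1.5 times (or the spread) and 34 moved. Among list tests 1244 kept direction and side of the threshold, 30 lost and 45 gained a call and 1 turned; among named genes 3737, 138, 39 and 8. Planned normexp background called far fewer genes, and a few spots had local backgrounds up to 65295 (medians 37 to 44), which stretched its fit. With it guard cells over leaf gave 2833 higher and 3312 lower, ABA 1635 and 1779, humidity 546 and 322, the difference 1410, the overlap 338 and r 0.069. With capped backgrounds, of these counts only genes lower in guard cells moved from the main fit (9123). Genes called were then 14966, 7045, 2927 and 4172 for guard cells over leaf, ABA, humidity and the difference. The main fit called 13782, 7445, 2811 and 4304. The median shift gave 5107 and 8958 for guard cells over leaf, since it moves every gene alike. Slide as a random block (correlation 0.08 and 0.116) gave 1877 and 1437 for ABA, 2076 for the difference and 511 for the overlap. Only the arrays compared gave 2150 lower with ABA and 2058 lower in dry air, and array weights 2673 and 2813 in dry air and an overlap of 1699; for these the cause was not tested. By construction, stricter thresholds gave fewer: under 0.01, 2586 lower with ABA, 814 and 573 in dry air, 2170 for the difference and 542 for the overlap; at least 2-fold, 3724 and 2039, 1427 and 596, 590 and 266, 1695 and 325.

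Values that turned were POLAR (-0.02) and NCED5 (-0.01) in guard cells over leaf, MAH1 with ABA (-0.113) and AT4G26820 (0.001), AT5G58784 (0.232) and AT2G25770 (0.574) in dry air, all with normexp; RBCS1A in guard cells over leaf with quantile normalization (0.081) and in the value table (0.134); and the ABA signalling kinases in guard cells over leaf, which fry called upwards (adjusted p = 0.00929) though their median was -0.116. With capped backgrounds no named gene turned, so the normexp turns came with the few spots of high local background. For the RBCS1A and kinase values the cause was not tested. Leaving out each array gave 7352 to 7873 higher and 5246 to 5763 lower in guard cells over leaf, 2790 to 3842 and 3275 to 4299 with ABA, 1116 to 1243 and 919 to 1028 in dry air, 3366 to 5404 for the difference, r of 0.275 to 0.346 and an overlap of 845 to 1119.

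Replicate as a block (9 residual degrees of freedom) gave 7919 and 5642 for guard cells over leaf and 1423 and 1156 in dry air, where samples share only a number: same-number correlations were -0.16, -0.447, -0.144 and 0.037, and 0.037, 0.085, -0.014 and -0.08, with no array of guard cells and leaf closest to its own number. Guard cell replicate 3 correlated at 0.529 with a leaf array of another number. The numbers are each sample's place in its group. The sample titles carry numbers that start at another value in each of these groups. Pairing by those was not checked, so a pairing of these samples stays open. In the ABA comparison it changed no other call among named genes and lists than those given with the results. Slide and scan date blocks could not be fitted for guard cells over leaf, nor slide for humidity, and list tests with slide as a random block were not run.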

Other observations

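The families in this part and the other iron genes were chosen after the gene results were seen. The test of the glutathione transferases was written down before its own result was seen, on a pattern noticed in the data, and its check with capped normexp was chosen after that result was seen.

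Water channels and growth genes showed further differences between tissues and treatments. Aquaporins were lower in guard cells over leaf, 10 of 13 lower and 1 higher (median log2 -0.85, and -0.399 with quantile normalization, adjusted p over 9 families 0.00153, and adjusted p = 0.679 with an estimated correlation), with PIP2B at -1.73. In dry air 7 of 13 rose and 0 fell (median 0.50, adjusted p = 3.06e-06, and adjusted p = 0.102 with an estimated correlation), among them RD28 (3.18), PIP2B (1.97) and PIP2;5 (1.68). With ABA 2 were higher and 4 lower (adjusted p = 0.57), and the ABA effect minus the humidity effect was negative (median -0.60, 7 lower and 1 higher, adjusted p = 0.0019, and adjusted p = 0.49 with an estimated correlation). The auxin-induced SAUR genes were lower with ABA, 10 of 16 lower and 1 higher (median -1.21, adjusted p = 0.00105, and adjusted p = 0.338 with an estimated correlation), SAUR29 at -2.27 and SAUR15 at -1.55 with SAUR36 at 1.94. In dry air 0 of the 16 were called by limma in either direction (median -0.16), and the ABA effect minus the humidity effect was negative (median -1.07, 4 lower and 1 higher, adjusted p = 0.0161, and adjusted p = 0.49 with an estimated correlation). In guard cells over leaf 9 of 16 were lower and 1 higher (median -1.05, adjusted p = 0.0361, and adjusted p = 0.684 with an estimated correlation). Expansins had 2 higher and 9 lower of 27 with ABA and did not pass (median 0.23, which turned to -0.177 with quantile normalization, adjusted p = 0.0872), while the ABA effect minus the humidity effect was negative (median -0.56, and -0.338 with capped normexp, 7 lower and 0 higher, adjusted p = 0.0175, and adjusted p = 0.49 with an estimated correlation). Xyloglucan endotransglucosylases had 9 higher and 4 lower of 28 with ABA (median 0.67, and 0.215 with capped normexp, adjusted p = 0.0374, and adjusted p = 0.338 with an estimated correlation), opposite to XTH31 (-4.43). Heat shock factors had 6 higher and 1 lower of 20 with ABA (median 0.34, adjusted p = 0.0374, and adjusted p = 0.338 with an estimated correlation). Late embryogenesis genes rose in both, 5 of 6 with 0 lower each time (median 1.76 with ABA, adjusted p = 0.00105, and adjusted p = 0.177 with an estimated correlation, and 2.25 in dry air, where adjusted p = 0.0295 with an estimated correlation and the median was 1.097 with capped normexp).

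Iron storage genes were higher in dry air (4 ferritins, adjusted p over 2 iron sets 6.54e-06, and adjusted p = 0.00634 with an estimated correlation). FER1 (2.72), FER3 (1.31) and FER2 (0.64) rose and FER4 was at 0.84 (adjusted p = 0.0508). FRO3, an iron reductase, fell (-2.18, adjusted p = 0.000896), and so did BTS, a brake on the iron response (-1.54, adjusted p = 0.000138), whereas FRO2 (1.99) and NAS1 (1.30) rose, 3 lower and 2 higher of 9 iron deficiency genes outside the bHLH38 group, which did not pass as a list (adjusted p = 0.214). The ABA effect minus the humidity effect was 3.79 for bHLH38, 4.20 for bHLH39 and -1.76 for FER1.

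Control spray guard cells of gl1-1 and high humidity guard cells of Col-0 were also set against leaf. Guard cell genes had medians of 2.94 and 2.44 and mesophyll genes of -1.46 and -1.11, beside 2.62 and -1.25 in the untreated guard cells, with the same leaf arrays below all 3 groups, so these values are not independent.

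Glutathione transferases of the tau class rose with ABA, 12 of 25 higher and 4 lower (median 0.75, adjusted p = 0.00105, and adjusted p = 0.177 with an estimated correlation), led by GSTU9 (5.35), GSTU25 (4.03) and GSTU24 (3.99). As a hypothesis, the ABA solution may give, beyond the control spray, a detoxification response that dry air does not. The conditions recorded for the control spray do not state whether it held Triton X-100, so ABA and Triton cannot be told apart. In the test, the median ABA effect minus humidity effect of the 24 members other than GSTU9 was 0.506, with 8 differing upwards and 1 downwards (adjusted p of the whole family = 0.49 with an estimated correlation). That is just above the bound of 0.5 set for it, but with capped normexp the median was 0.277, so the test leaves the hypothesis open. Genotype differs between the experiments, and the hypothesis was found and tested on the same data.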
